A study of Homo sapiens with 16 samples.

How the data were processed

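RNAPII was measured by ChIP-seq with the N-20 antibody in MCF10A-MYC-ER cells in 4 groups of 2 libraries: control, MYC (200 nM 4-hydroxytamoxifen), shUVSSA and MYC+shUVSSA. The 8 input libraries that the labels list were not analysed here, so no value is corrected for input. Per the labels, the authors used featureCounts of the Subread package with the hg19 build, and the deposited values are raw read counts per window, with no normalization. The aligner, the versions, and the handling of duplicates, reads with several alignments and overlapping windows are not stated. The control and UVSSA hairpins are in separate derivatives of the line, and the labels do not say whether replicates were separate cultures or whether a replicate number marks a shared day.

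The files held 57034 windows for 28517 genes, a promoter window reaching 300 bp to either side of the start and a body window from 301 to 3000 bp downstream (3 were of another length). Gene symbols were matched to current names: 20941 were current, 1958 were older names and 5618 stayed unmatched and were kept under the name in the files. Promoter windows were wholly covered by another window in 13.9% and in part in 9.10% of genes, and body windows in 7.86% and 10.1%. The wholly covered windows were at 0 in all 8 libraries, so a 0 there says nothing about RNAPII. Counts over the windows ranged from 819159 to 1665671 per library, and a floor of 3 counts was 1.80 to 3.66 CPM. Replicates of a group differed by more than counting error, with a chi-square per degree of freedom of 3.91 (control), 6.08 (MYC), 6.00 (shUVSSA) and 6.19 (MYC+shUVSSA). The biological coefficient of variation in edgeR was 39.7% for tested body windows and 56.1% for promoter windows, and 20.9% and 32.1% for active windows.

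The choices fixed before the data were examined were as follows. Promoter and body windows were tested apart with edgeR quasi-likelihood models (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM scaling, filterByExpr, group as the only term, robust fitting and all 8 libraries, which left 24144 body and 10796 promoter windows. The comparisons were MYC against control, shUVSSA against control, MYC+shUVSSA against each of MYC, shUVSSA and control, and the interaction, and a window was called at a Benjamini-Hochberg adjusted p under 0.05. Of 30 gene lists written from general knowledge, 29 were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, and again with an estimated correlation and with fry. Their members were also tested gene by gene, with p adjusted over the list alone, which does not correct for the number of lists, comparisons and kinds of window. The remaining list, of genes of other tissues, served as a second background. EIF4A1 (MYC-induced list) and XBP1S (luminal list) were not found among the symbols, and NF-kB members numbered 24 of 25.

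Active genes were those whose mean count per kb over the 8 libraries was above 3 times that of the olfactory receptor genes, which served as silent background (391 promoter and 385 body windows that no other window overlapped). RNAPII enrichment was the median count per kb of active genes over that of the background, compared between groups by exact permutation of libraries, and after the data were seen also over all 8 libraries at once. Effects of MYC with and without shUVSSA, and of shUVSSA with and without MYC, were correlated across windows.

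After the fixed test had called 0 windows, active nuclear genes (1833 body and 3316 promoter windows) were fitted with the replicate number as a block. This fit was chosen because the first principal component of active body windows (30.1% of the variance) separated the replicate numbers. Deviations of libraries with the same number from their group means correlated at 0.218 to 0.442 across active bodies, but at -0.00677 to 0.0688 across all tested bodies. Active promoters were given the same block, although their first component (25.1%) did not separate the numbers and their deviations correlated above 0.1 in 1 of 6 pairs of groups (0.0310 to 0.133). The promoter-to-body ratio per gene, voom with quality weights, windows free of overlap and the exclusion of 2 libraries together were also added after the data were seen. Genes with a symbol known to the reference were named by a rule. Of those that passed among active genes, up to 6 per direction with the largest log2 change were named where the libraries of the 2 groups did not overlap and the log2 CPM was at least 2, with every member of a gene list that passed. Over all windows, the 3 per direction with the smallest p were named (5 for the interaction). Values of list members are those of the most abundant 3. AKR1C1 was named in addition. The promoter-to-body ratio used 3392 genes active in either window and free of overlap in both.

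Alternatives were DESeq2 1.42.0, total counts and background scaling in place of TMM, loess offsets against abundance, no filter, active genes alone or above 10 times background, the replicate block, and leaving out each library in turn, in which case a lone library was taken to vary like the other groups. A trend with gene length was planned but could not be run, because the body windows are all of 1 length but for 3. Tests on simulated data with changed genes in 1 comparison (MYC+shUVSSA against MYC) recovered 13.6% of 4-fold and 1.52% of 2-fold changes in body windows with the fixed test. The fit of active genes with the block recovered 98.5% of 4-fold and 43.9% of 2-fold changes, with 2 false calls. For promoters the shares at 4-fold were 10.6% and 37.9%. A histone list shifted 1.5-fold was found by camera with the preset correlation at adjusted p = 1.17e-07 with 0 other lists called. The simulated genes varied independently, so this does not test the preset correlation where genes share deviations. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.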

Results

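RNA polymerase II (RNAPII) on chromatin was measured by ChIP-seq in MCF10A-MYC-ER cells, a non-tumorigenic human mammary epithelial line that carries MYC fused to an oestrogen receptor hormone-binding domain. The fusion is switched on with 200 nM 4-hydroxytamoxifen. UVSSA, a factor of transcription-coupled DNA repair that acts on stalled RNAPII, was knocked down with a short hairpin (shUVSSA), and a control hairpin served the other cells. The 4 groups were control, MYC, shUVSSA and MYC+shUVSSA, each with 2 immunoprecipitated libraries, and 8 input libraries were not analysed here. Each of 28517 genes had a promoter window reaching 300 bp to either side of its start and a body window of 2700 bp just downstream. The windows of replicate 1 held 956860 (control), 1512069 (MYC), 1344653 (shUVSSA) and 1334697 (MYC+shUVSSA) reads, and those of replicate 2 held 1665671, 1385400, 1316377 and 819159 reads in the same order. These are totals over the windows and not the depth of the whole libraries. Between 18.6% and 31.5% of windows were at 0 in a library, and a floor of 3 counts stood at 1.80 to 3.66 CPM (counts scaled to library size), which covers counting error only.

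The test fixed before the data were examined, edgeR over all windows past a low-count filter, called 0 of 24144 body windows and 0 of 10796 promoter windows in each of the 6 comparisons. Single genes are therefore said below to have risen or fallen where they passed edgeR on 1833 active body windows or 3316 active promoter windows with the replicate number as a block, a fit chosen after the data were seen. Their values are CPM among the active windows of their kind, and values of list members are CPM among all tested body windows, each as mean ± SD with n = 2 libraries. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p values measure a spread that may be technical in part.

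RNAPII at the targeted genes themselves was sparse. At UVSSA (hg19, chromosome 4, promoter window 1340803 to 1341403), the promoter window held 4 and 19 counts in control, 14 and 6 in MYC, 1 and 7 in shUVSSA and 6 and 1 in MYC+shUVSSA libraries. That was 43.8 ± 26.5 CPM in control against 19.1 ± 20.6 CPM in shUVSSA libraries among all tested promoter windows, a log2 difference of -1.20 (SE 1.53, adjusted p = 0.999) that was smaller than its error. Its body window (1341404 to 1344103) stood at 17.1 ± 0.119 CPM in control and 28.3 ± 14.7 CPM in shUVSSA libraries. A hairpin acts on the transcript after RNAPII has made it, so these values do not measure the knockdown. At the endogenous MYC gene (chromosome 8), the promoter window was wholly covered by another window and held 0 counts in all libraries for that reason. The MYC body window, 81.4% covered, held 47 and 17 counts in control, 87 and 29 in MYC, 92 and 13 in shUVSSA and 83 and 12 in MYC+shUVSSA libraries, and passed in no comparison.

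RNAPII over active genes stood above the background of the silent olfactory receptor genes in every library. Their selection against the same background in the same 8 libraries largely fixed this, so only differences between libraries are informative. The median body enrichment over 1837 active genes was 3.75 ± 0.408 in control, 5.39 ± 1.80 in MYC, 4.18 ± 0.790 in shUVSSA and 3.67 ± 0.545 in MYC+shUVSSA libraries. The promoter enrichment over 3319 active genes was 4.92 ± 0.639, 6.63 ± 2.29, 4.67 ± 0.945 and 3.58 ± 0.843 in the same order. MYC replicate 1 stood apart, at 6.66 for bodies against 4.11 in MYC replicate 2 and at 8.25 against 5.01 for promoters. The planned exact two-sided permutation test of 2 against 2 libraries cannot go below p = 0.333 and so cannot decide whether groups differ. Exact permutation tests over all 8 libraries, added after the data were seen, gave p = 0.400 for bodies and 0.229 for promoters for any difference among the 4 groups (105 splits). For the 4 libraries with shUVSSA against the 4 without, the exact permutation p was 0.543 for bodies and 0.0857 for promoters (log2 -0.19 and -0.47, 70 splits). With genes of other tissues as background it was 0.857 and 0.657 (log2 -0.05 and -0.21). For the libraries with MYC against those without, on the olfactory receptor background, the exact permutation p was 0.629 and 1. Scaling to the olfactory receptor genes in place of TMM would shift the median body window by 0.16 (log2) for MYC against control, -0.37 for MYC+shUVSSA against MYC, -0.14 for MYC+shUVSSA against shUVSSA and -0.20 for MYC+shUVSSA against control. The promoter shifts would be 0.34, -0.75, -0.36 and -0.41. Scaling to total counts would shift the body median by -0.13 for MYC against control, and all changes below are relative to the TMM scale.

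**Figure D1:**
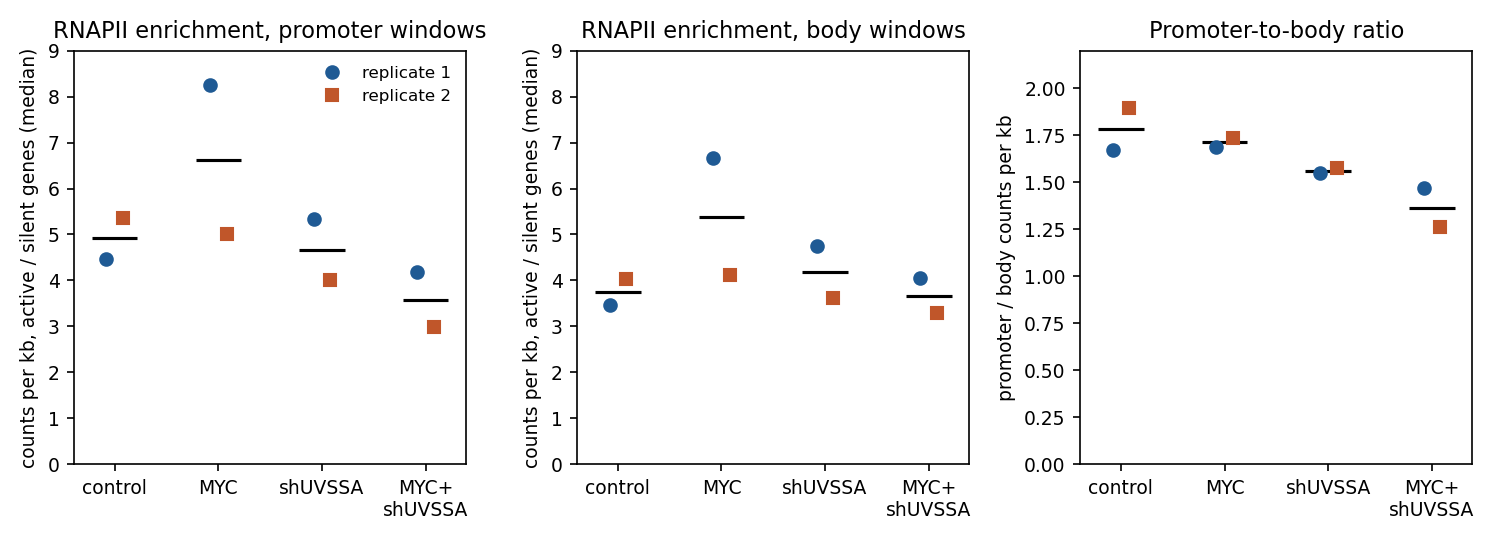
RNAPII enrichment of active over silent genes (median of counts per kb over counts per kb of olfactory receptor genes) in promoter and body windows, and the promoter-to-body ratio of counts per kb, by group. Points are libraries and bars are group means; MYC replicate 1 had the highest enrichment (8.25 at promoters), and the 4 libraries with shUVSSA had promoter-to-body ratios of 1.26 to 1.58 against 1.67 to 1.89 in the others.

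MYC against control asked what induction of MYC does to RNAPII on genes in cells with intact UVSSA. The drug that switches on the fusion was given to all libraries with MYC and to none of the others. No group received the drug without the fusion, so an effect of MYC cannot be told apart from an effect of the drug itself. That limit holds for every comparison below of libraries with MYC against libraries without, and for the interaction. RNAPII rose over the body of DDIT4 (chromosome 10, 74033977 to 74036676), a stress-induced inhibitor of mTORC1 signalling, from 229 ± 140 CPM in control to 647 ± 46.1 CPM in MYC libraries (log2 1.61, SE 0.33, adjusted p = 0.00206, higher in both replicates). The ribosomal protein genes were called higher as a list by camera with a preset correlation, with 62 of 65 members above 0 and a median log2 of 0.53 (adjusted p = 1.51e-11). They were not called with an estimated correlation (adjusted p = 0.363 with an estimated correlation) or with loess offsets against abundance (median 0.14, adjusted p = 0.151). In total 13 body lists were called with the preset correlation and 0 with the estimated one (0.327 for nucleotide synthesis, 0.467 for NF-kB and 0.363 for the other 11). RPS23 stood at 501 ± 83.5 CPM in control and 705 ± 347 CPM in MYC libraries. Genes commonly listed as induced by MYC were called higher too (39 of 46 above 0, median 0.43, adjusted p = 1.13e-06). The nucleolar proteins among them had NPM1 at 311 ± 50.9 against 588 ± 130 CPM and NCL at 184 ± 17.1 against 325 ± 107 CPM. Purine and pyrimidine synthesis genes were called higher (21 of 24 above 0, median 0.49, adjusted p = 0.000178). Among them PAICS, a purine synthesis enzyme, stood at 84.5 ± 5.47 against 128 ± 5.34 CPM and MTHFD2, an enzyme of mitochondrial folate metabolism, at 77.1 ± 0.274 against 136 ± 11.6 CPM.

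Ribosome biogenesis factors (43 of 56 above 0, median 0.33, adjusted p = 0.000178), splicing factors (32 of 40, 0.34, 8.35e-06) and proteasome subunits (22 of 30, 0.35, 0.0209) were called higher in MYC than in control libraries as well. Stress and signalling lists were also called: immediate early genes (23 of 28, 0.41, adjusted p = 0.00483), the integrated stress response (14 of 18, 0.39, 0.00634), NF-kB and inflammatory genes (18 of 24, 0.33, 0.0461) and sterol synthesis genes (18 of 22, 0.29, 0.0227). FOS, an immediate early transcription factor, stood at 529 ± 132 CPM in control and 1111 ± 858 CPM in MYC libraries, and the chemokine gene CXCL2 at 1742 ± 428 and 3422 ± 2937 CPM. Genes commonly listed as repressed by MYC were called higher (20 of 29 above 0, median 0.46, adjusted p = 0.0213), with the Notch effector HES1 at 973 ± 334 and 2214 ± 1459 CPM. Without MYC replicate 1 the medians turned to -0.02 for these genes, -0.08 for immediate early genes and -0.17 for NF-kB genes, so their direction rested on that library. Replication-dependent histone genes were called higher on the TMM scale (28 of 30, median 0.47, adjusted p = 3.81e-06), although offsets fitted against abundance turned the medians of the histone list to -0.09 and of the NF-kB list to -0.12. Blood and immune markers, which these cells should not express, were called lower by camera (18 of 21 below 0, median -0.50, adjusted p = 0.0213). PTPRC among them hardly differed, at 82.6 ± 31.8 CPM in control and 81.1 ± 11.1 CPM in MYC libraries.

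With loess offsets 3 of these 13 lists stayed called: MYC-induced genes (adjusted p = 0.00573), nucleotide synthesis and the integrated stress response (0.0316 each). No member passed edgeR over all windows, and 1, DDIT4 in the integrated stress list, passed when adjusted over the list alone (adjusted p = 0.00768). That adjustment covers 1 list in 1 comparison at a time. Across the 29 lists and 6 comparisons, some such passes, here and below, can arise by chance. At an unadjusted p under 0.05, edgeR gave 351 body windows higher and 330 lower, and 94 promoter windows higher and 114 lower, while DESeq2 called 0 of either kind. The body windows with the smallest p that did not pass were AGPAT5, TFRC and DDIT4 (higher) and PHGR1, LAMC3 and CAPG (lower). TFRC, the transferrin receptor, stood at 53.7 ± 3.83 CPM in control and 145 ± 6.79 CPM in MYC libraries. At promoters 0 lists were called, and the smallest p values belonged to OR5K4, PDK4 and TAF4B (higher) and to CLDN8, CACNA2D1 and CLDN10-AS1 (lower). Without MYC replicate 1 the count of called lists fell from 13 to 4 and DDIT4 was lost, and without control replicate 1 the lists numbered 8. Without control replicate 2 or MYC replicate 2 they numbered 20 with 6 and 5 at promoters. The ribosomal protein, MYC-induced and nucleotide synthesis calls held without each of the 8 libraries. The calls of histones, immediate early, proteasome, sterol and blood genes were lost without control replicate 1 or MYC replicate 1, and those of splicing, ribosome biogenesis and integrated stress genes without MYC replicate 1. MYC-repressed genes were lost without MYC replicate 1 or control replicate 2, and NF-kB genes without these or MYC+shUVSSA replicate 2. The 1 call among active bodies became 5 without MYC replicate 2 and 2 without either control library. Among active promoters edgeR called 0, but 4 without control replicate 1, 2 without control replicate 2 and 1 without MYC replicate 2. DDIT4 was also lost without control replicate 2 or MYC replicate 2, and 76.9% of its body window was covered by another window.

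shUVSSA against control asked what the UVSSA hairpin does without MYC induction. The hairpins are in separate derivatives of the line, so the hairpin cannot be told apart from other differences between these. RNAPII fell over the body of PLAU (chromosome 10, 75671162 to 75673861), which encodes the urokinase plasminogen activator, from 1523 ± 978 CPM in control to 525 ± 18.7 CPM in shUVSSA libraries (log2 -1.35, SE 0.26, adjusted p = 0.000583). The change was -2.03 within replicate 1 and -0.69 within replicate 2. Growth lists were called slightly higher by camera with a preset correlation: ribosomal proteins (54 of 65 above 0, median 0.26, adjusted p = 0.00249), ribosome biogenesis (39 of 56, 0.21, 0.0363), MYC-induced genes (32 of 46, 0.24, 0.0368) and nucleotide synthesis (19 of 24, 0.24, 0.0363). None was called with an estimated correlation (adjusted p = 0.605 with an estimated correlation for nucleotide synthesis, 0.888 for the other 3) or with loess offsets. G2 and mitosis genes were also called higher (21 of 30, median 0.33, adjusted p = 0.0177, but adjusted p = 0.605 with an estimated correlation). The mitotic kinase CDK1 stood at 89.1 ± 18.4 CPM in control and 131 ± 11.2 CPM in shUVSSA libraries, and the mitotic spindle gene HMMR at 189 ± 40.1 and 231 ± 19.4 CPM. Histone genes were called higher (27 of 30, median 0.26, adjusted p = 0.0222, but adjusted p = 0.888 with an estimated correlation), with HIST1H1C, a linker histone gene, at 772 ± 60.4 and 920 ± 0.349 CPM.

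With loess offsets 0 of these 6 lists were called. Among list members, 0 body windows passed edgeR when adjusted over the list alone. The promoter windows of MED14, a subunit of the Mediator complex, and of the monocyte marker CD14 passed (log2 4.22 and -2.69, adjusted p = 0.0325 and 0.0249). Adjusted over all promoter windows, the edgeR p was 0.999 for both. At an unadjusted p under 0.05 there were 332 body windows higher and 434 lower, and 148 promoter windows higher and 180 lower, and DESeq2 called 0. The smallest p values belonged to ECI1, TAS2R20 and LRRC72 (higher) and YTHDC2, OR4K13 and OR10C1 (lower) among bodies, and to OR5K4, MED14 and KCTD9 (higher) and MGRN1, CD96 and KRTAP19-4 (lower) among promoters. Of the active promoter windows 1, of a transcript with no official symbol, rose. Without control replicate 1 or shUVSSA replicate 1, 0 lists were called and PLAU was lost. The list count was 2 without either MYC+shUVSSA library and 11 without control replicate 2. The 1 call among active bodies became 2 without either MYC library or MYC+shUVSSA replicate 1, and the 1 promoter call became 9 without control replicate 1 and 0 without either MYC or either shUVSSA library.

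MYC+shUVSSA against MYC asked what the UVSSA hairpin does to RNAPII once MYC is induced. Among active genes with the replicate block, 22 body windows rose and 22 fell. RNAPII rose over AKR1C2 (chromosome 10, 5043206 to 5045905), an aldo-keto reductase of steroid metabolism, from 497 ± 268 CPM in MYC to 1564 ± 948 CPM in MYC+shUVSSA libraries (log2 1.62, SE 0.26, adjusted p = 1.59e-06). The change was 1.52 and 1.69 within the replicates, and the call was kept without each of the 8 libraries. Its close paralog AKR1C1, chosen after its values were seen, rose as well (log2 0.92, adjusted p = 0.0288), and reads shared between the pair cannot be told apart here. Other rises included MRPL44, a mitochondrial ribosomal protein gene (1.39, adjusted p = 0.0268), CCNK, the cyclin partner of the elongation kinases CDK12 and CDK13 (1.35, 0.0288), ANKRD18B (1.37, 0.0277), the pseudogene KRT121P (1.26, 0.0227) and the MIR3120 window (1.38, 0.0288).

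RNAPII fell over PLAU (log2 -1.41, adjusted p = 7.71e-05) and over the window of MIR4260 (chromosome 1, 209793855 to 209796554), which lies inside LAMB3, the gene of a laminin chain of the epithelial basement membrane. That window fell from 1344 ± 65.9 CPM in MYC to 505 ± 161 CPM in MYC+shUVSSA libraries (log2 -1.45, SE 0.26, adjusted p = 2.89e-05, kept without each of the 8 libraries). Further falls included POP5, a subunit of RNase P (-1.39, adjusted p = 0.0277), ITPKC, an inositol trisphosphate kinase (-1.29, 0.00800), SGMS2, a sphingomyelin synthase (-1.12, 0.0277), and LPPR3 (-1.40, 0.0288). Members of the fixed lists that fell were JUN, an AP-1 transcription factor (from 2835 ± 1431 to 1320 ± 302 CPM, log2 -1.06, adjusted p = 0.00800) and the antiproliferative gene BTG1 (-0.91, 0.0348). XBP1, a transcription factor of the unfolded protein response, fell from 694 ± 19.5 to 371 ± 268 CPM (log2 -1.04, adjusted p = 0.0300).

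Over all tested body windows, 5 lists were called lower in MYC+shUVSSA than in MYC libraries by camera with a preset correlation, and 0 with an estimated correlation or with loess offsets. Ribosomal protein genes were called lower (63 of 65 below 0, median -0.43, adjusted p = 1.16e-06), but not with an estimated correlation (adjusted p = 0.637 with an estimated correlation) or with loess offsets (median -0.15, adjusted p = 0.109). They had RPS23 at 705 ± 347 CPM in MYC and 447 ± 48.4 CPM in MYC+shUVSSA libraries. Replication-dependent histone genes were called lower (28 of 30, median -0.59, adjusted p = 1.24e-05), but not with an estimated correlation (adjusted p = 0.637 with an estimated correlation) or with loess offsets (median -0.17, adjusted p = 0.318). They had HIST1H1E at 1306 ± 524 and 690 ± 13.6 CPM and HIST1H1C at 1079 ± 401 and 559 ± 50.9 CPM. Endoplasmic reticulum chaperones and unfolded protein response genes were called lower (14 of 19, median -0.55, adjusted p = 0.0273), with the chaperone HSPA5 at 384 ± 165 and 181 ± 100 CPM. Immediate early genes (24 of 28, -0.46, 0.00247) and NF-kB and inflammatory genes (18 of 24, -0.54, 0.0265) were called lower too, although loess offsets turned the NF-kB median to 0.17. At promoters 4 of these 5 families were called lower, with medians of -0.31 for ribosomal proteins, -0.46 for histones, -0.41 for chaperones and -0.40 for immediate early genes. None of the 8 promoter lists was called with an estimated correlation (adjusted p = 0.352 to 0.546 with an estimated correlation) or with loess offsets. The promoters of heat shock (-0.56), aminoacyl-tRNA synthetase (-0.35) and sterol synthesis genes (-0.58) were called lower, while those of 7 blood and immune markers were called higher (0.74, adjusted p = 0.0456). That last call was kept in 1 of 8 fits without a library, and with the replicate block neither it (adjusted p = 0.0510) nor the tRNA synthetase call (0.0548) was kept, which left 6 of the 8 promoter lists.

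With an estimated correlation the adjusted p was 0.637 for the other 3 body lists as well. On active genes with the replicate block, tested at the preset correlation only, the histone list was the one still called lower (25 members, median -0.38, adjusted p = 0.000841). That call was lost without MYC replicate 1 (median -0.23, adjusted p = 0.151), when 0 lists were called in this fit, or without MYC+shUVSSA replicate 2 (-0.28, 0.0554). Adjusted over the list alone, 2 body windows of the DNA replication and G1/S list passed higher: CLSPN, a replication checkpoint adaptor (log2 1.56, adjusted p = 0.0246), and PRIM1, a DNA primase subunit (1.75, 0.0246). At promoters, 8 members passed lower when adjusted over the list alone, among them MANF, a secreted reticulum stress protein, and NFKBIA, an inhibitor of NF-kB (log2 -1.26, adjusted p = 0.0123). The collagen crosslinker LOX passed higher. The promoter of SLC10A5, a solute carrier gene, held 25 and 42 counts in MYC and 0 in both MYC+shUVSSA libraries. Set against a floor of 3 counts per library it was 6.64-fold lower, a bound for counting error only. In the MYC+shUVSSA libraries 40.9% (replicate 1) and 22.3% (replicate 2) of silent olfactory receptor promoters were at 0. A Poisson spread gives at most 0.921%, so zeros were more frequent than counting error allows. The pseudogene promoter MLLT10P1 rose (log2 1.98, adjusted p = 0.0102).

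Over all windows, an unadjusted p under 0.05 was reached by 770 body windows higher and 831 lower and by 326 promoter windows higher and 398 lower in MYC+shUVSSA against MYC, and DESeq2 called 1 body window (MIR4260, lower) and 6 promoter windows. Among the smallest p values over all windows were those of ZSWIM2, CCT6B and TMPRSS11F (higher) and OPN1SW, METTL1 and FICD (lower) among bodies, and of SLITRK4, CLDN8 and GNAT3 (higher) and SLC10A5 and MIR548AC (lower) among promoters. Without MYC replicate 1, the library of highest enrichment, the 44 calls among active bodies became 2, 0 lists were called in bodies or promoters, and PLAU was lost. MRPL44, ANKRD18B, SGMS2 and XBP1 were lost without either MYC library or MYC+shUVSSA replicate 1, JUN and ITPKC without MYC or MYC+shUVSSA replicate 1, and LPPR3 without either MYC library or MYC+shUVSSA replicate 2. CCNK, KRT121P and MIR3120 were kept in 4 of 8 such fits, and POP5, BTG1 and the promoters SLC10A5 and MLLT10P1 in 3 of 8. The ribosomal protein list was lost without MYC replicate 1, and the other 4 without that library or MYC+shUVSSA replicate 2. The 44 became 20 without MYC+shUVSSA replicate 1 and 24 without MYC replicate 2. The body lists became 11 without MYC replicate 2 and 1 without MYC+shUVSSA replicate 2, and the promoter lists 14 and 1. Without MYC+shUVSSA replicate 2 the test over all windows rested on 1 library of that group, the one with the most windows at 0 (31.5%). The body windows it called were mostly falls, the largest log2 -9.23 (SETDB2), with few rises (BC067268, 3.04). Zeros in 1 library can give such falls, so in no comparison are the calls without MYC+shUVSSA replicate 2 evidence of a change. The 2 promoter calls became 39 without that library, 8 without either control library, 1 without MYC+shUVSSA replicate 1 and 0 without either MYC or either shUVSSA library.

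**Figure D2:**
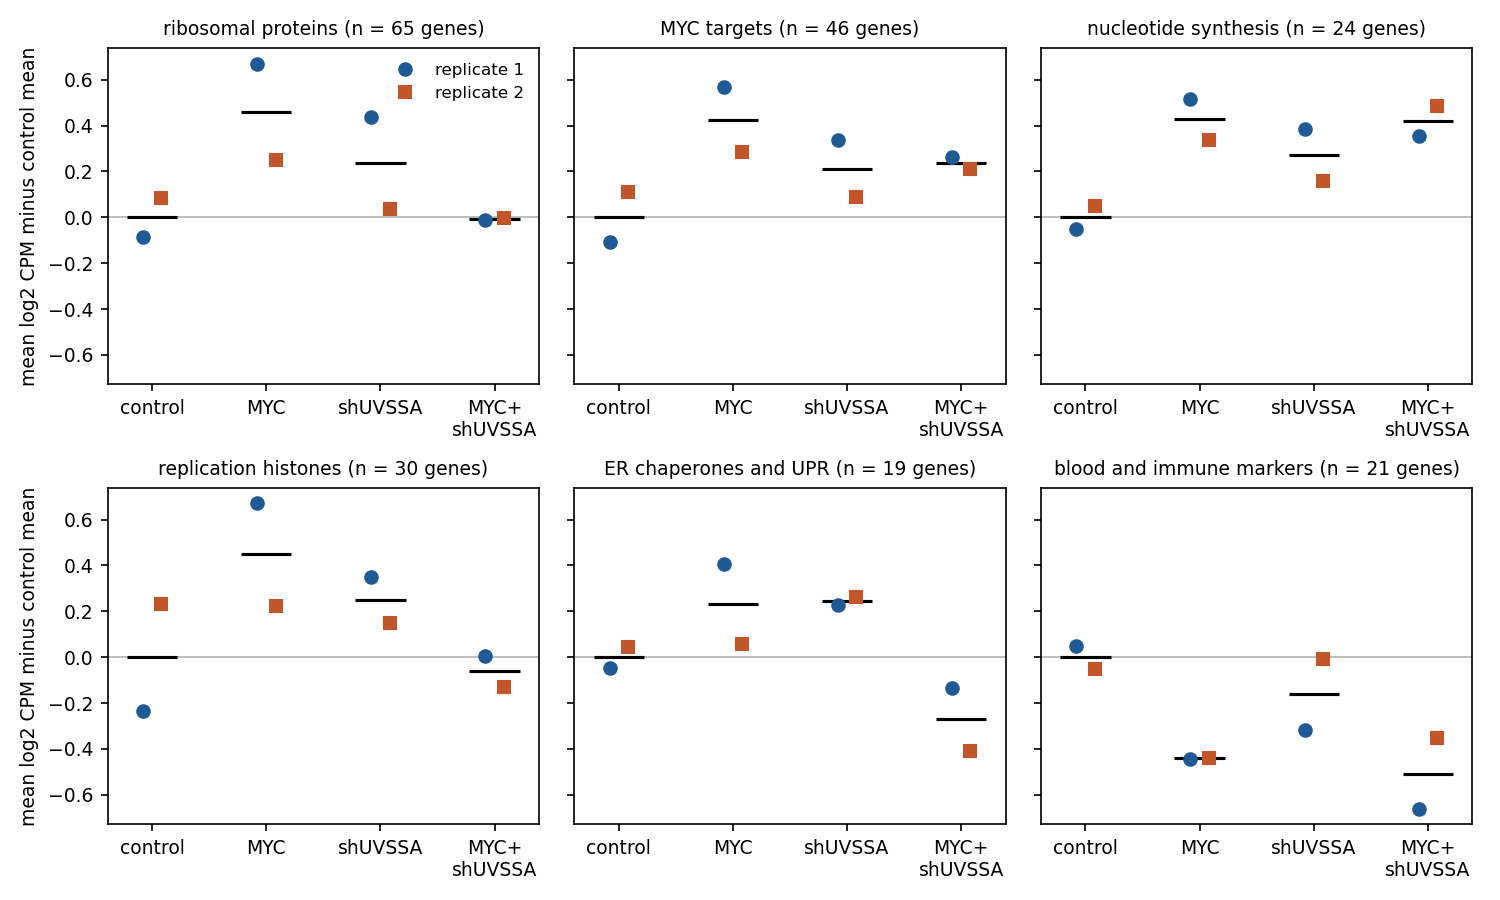
Mean log2 CPM of the body windows of 6 gene lists in each library, relative to the mean of the control libraries, by group. Points are libraries and bars are group means; MYC replicate 1 lies above MYC replicate 2 in the lists called higher, and the histone list is lower in both MYC+shUVSSA libraries than in both MYC libraries.

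MYC+shUVSSA against shUVSSA asked what MYC induction does in cells with the UVSSA hairpin. RNAPII rose over SIK1 (chromosome 21, 44844002 to 44846701), a salt-inducible kinase gene that responds to cyclic AMP, from 622 ± 383 CPM in shUVSSA to 1596 ± 151 CPM in MYC+shUVSSA libraries (log2 1.53, SE 0.26, adjusted p = 1.56e-05). The change was 0.93 and 2.06 within the replicates. ANGPT1, which encodes the TIE2 ligand angiopoietin 1, rose from 357 ± 104 to 827 ± 56.5 CPM (log2 1.23, adjusted p = 0.0440). RNAPII fell over CSF3, the gene of granulocyte colony-stimulating factor (940 ± 113 to 442 ± 197 CPM, log2 -1.14, adjusted p = 0.0159), and over the MIR4260 window inside LAMB3 (-1.14, 0.0127). Histone genes were called lower by camera with a preset correlation (26 of 30 below 0, median -0.45, adjusted p = 0.0287), as were chaperone genes (15 of 19, -0.45, 0.0394) and ribosomal protein genes (53 of 65, -0.28, 0.0487). None of the 3 was called with an estimated correlation (adjusted p = 0.978 with an estimated correlation) or with loess offsets. At promoters the 15 chaperone genes were all below 0 (median -0.66, adjusted p = 0.00708) and 7 blood and immune markers were called higher (1.38, 0.0327), the latter in 0 of 8 fits without a library.

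With an estimated correlation the adjusted p was 0.759 for the 2 promoter lists. On active genes with the replicate block, camera at the preset correlation called the histone list (median -0.37, adjusted p = 1.50e-05). The estimated correlation was not tried in that fit. The histone median there ranged from -0.43 to -0.32 as each library was left out. Of the list members, 3 body windows passed when adjusted over the list alone. RPA3, a subunit of the single-strand binding complex of repair and replication, was higher (log2 2.30, adjusted p = 0.0323). The ATP synthase gene ATP5A1 (-1.76, 0.0267) and the sterol synthesis gene MVD (0 counts in both MYC+shUVSSA libraries) were lower. The SLC10A5 promoter, at 0 in both MYC+shUVSSA libraries, was 7.43-fold lower against the same floor, which covers counting error only. The MIR3945 promoter fell (-1.75, adjusted p = 0.0167) and PRKD3, a protein kinase D gene, rose from 0 and 5 counts to 89 and 22. Adjusted over the list alone, those that passed included the promoters of MANF, KRT6B and PSMC5 (lower) and of POSTN and CD14 (higher).

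Over all windows edgeR gave 774 body windows higher and 786 lower and 306 promoter windows higher and 364 lower at an unadjusted p under 0.05 for MYC+shUVSSA against shUVSSA, and DESeq2 called 0 body and 8 promoter windows. The smallest p values included those of OR4K13, AATF and ATP13A4 (higher) and FICD, SNORA54 and GUCY2D (lower) among bodies, and of PRKD3, MIR4503 and POSTN (higher) and SLC10A5 and MIR3945 (lower) among promoters. The 5 calls among active bodies became 0 without shUVSSA replicate 2, 1 without shUVSSA replicate 1 or MYC+shUVSSA replicate 1, 3 without control replicate 1 or MYC replicate 2, and 15 without MYC+shUVSSA replicate 2, when the test over all windows called 73. SIK1 was lost without shUVSSA replicate 2 or MYC+shUVSSA replicate 2, ANGPT1 was kept in 1 of 8 such fits, and CSF3 and MIR4260 were lost without either shUVSSA library or MYC+shUVSSA replicate 1. The 4 promoter calls became 21 without MYC+shUVSSA replicate 2, 2 without either MYC library or MYC+shUVSSA replicate 1, 1 without shUVSSA replicate 2 and 0 without shUVSSA replicate 1. PRKD3 was lost without shUVSSA or MYC+shUVSSA replicate 1, and SLC10A5 without these or shUVSSA replicate 2, while MIR3945 was kept in 3 of 8 fits. In turn 0 body lists were called without shUVSSA replicate 1 or MYC+shUVSSA replicate 2. The promoter lists became 0 without the same 2 libraries, 6 without MYC+shUVSSA replicate 1, and 1 without either control or either MYC library.

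MYC+shUVSSA against control set both changes against neither. SIK1 rose from 459 ± 347 to 1596 ± 151 CPM (log2 2.03, SE 0.27, adjusted p = 2.06e-10), with 1.27 and 2.77 within the replicates. AGPAT5, a lysophospholipid acyltransferase gene, rose from 143 ± 7.92 to 573 ± 38.6 CPM (log2 2.00, adjusted p = 0.000126). NAMPT, the enzyme that limits NAD salvage, rose from 364 ± 114 to 1008 ± 91.0 CPM (adjusted p = 5.82e-05), and ANGPT1 from 266 ± 142 to 827 ± 56.5 CPM (adjusted p = 7.30e-05). Further rises were those of AKR1C2 (1.46, 2.27e-05), the serum- and glucocorticoid-regulated kinase SGK1 (1.42, 5.82e-05), DDIT4 (1.25, 0.0172), the ribosome biogenesis factor WDR43 (1.17, 0.0127) and TFRC (1.23, 0.0480). RNAPII fell over LAMB3 itself (chromosome 1, 209822820 to 209825519) from 3487 ± 40.3 to 1471 ± 486 CPM (log2 -1.26, adjusted p = 0.000126). The MIR4260 window within it fell from 1789 ± 68.2 to 505 ± 161 CPM (-1.86, adjusted p = 1.96e-09).

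PLAU fell as well (log2 -1.73, adjusted p = 1.10e-07), and so did the cytokine genes CSF3 (-1.29, 0.000364) and IL1B (-1.15, 0.00129). Other falls were those of the stratifin gene SFN (-1.34, 0.0170), LPPR3 (-1.94, 0.000167), POP5 (-1.37, 0.0257) and the SNORD49A window (-1.46, 0.0212). In total 18 active body windows rose and 19 fell. Growth and replication lists were called higher by camera with a preset correlation: nucleotide synthesis (21 of 24 above 0, median 0.51, adjusted p = 0.00223), DNA replication and G1/S (22 of 30, 0.46, 0.00527), ribosome biogenesis (40 of 56, 0.28, 0.0115) and MYC-induced genes (32 of 46, 0.38, 0.0129). None was called with an estimated correlation (adjusted p = 0.382 with an estimated correlation for nucleotide synthesis, 0.496 for G1/S and 0.908 for the other 2), and with loess offsets nucleotide synthesis alone was (adjusted p = 0.0220). Active genes with the replicate block were tested at the preset correlation only. In that fit 3 of these lists were called higher, MYC-induced genes (median 0.37, adjusted p = 0.0223), nucleotide synthesis (0.62, 0.0423) and ribosome biogenesis (0.29, 0.0423), and histones were called lower (-0.27, 0.0223). The 3 were lost without either control library, and also MYC-induced genes without MYC+shUVSSA replicate 1, nucleotide synthesis without MYC+shUVSSA replicate 2 and ribosome biogenesis without either of these. The histone call was lost without control replicate 2 (median 0.01, adjusted p = 0.690) or MYC+shUVSSA replicate 2 (-0.16, 0.266). PAICS stood at 84.5 ± 5.47 CPM in control and 154 ± 13.8 CPM in MYC+shUVSSA libraries, and MCM7, a subunit of the replicative helicase, at 76.5 ± 9.84 and 108 ± 10.2 CPM. The promoters of chaperone genes were lower (14 of 15 below 0, median -0.82, adjusted p = 0.000843), with MANF at 21 and 23 counts in control and 0 and 1 in MYC+shUVSSA libraries.

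The chaperone promoters had adjusted p = 0.864 with an estimated correlation. Of the body members, ATIC, a purine synthesis enzyme gene, passed higher when adjusted over the list alone (log2 1.71, adjusted p = 0.0410) and MVD passed lower. The promoter members that passed lower included MANF, NFKBIA, LAMB3 and KRT6B. Over all windows edgeR gave 674 body windows higher and 711 lower and 269 promoter windows higher and 337 lower for MYC+shUVSSA against control at an unadjusted p under 0.05. DESeq2 called 2 bodies (AGPAT5 higher, MIR4260 lower) and 3 promoters. The smallest p values over all windows were those of AGPAT5, ANGPT1 and VIPR2 (higher) and OPN1SW, LPPR3 and TSPAN5 (lower) among bodies, and of OR6K6, SCN2A and GLUD1P3 (higher) and KRT6B, FAM43A and SLC10A5 (lower) among promoters. The 37 calls became 15 without control replicate 1 and 11 without control replicate 2, when NAMPT, AKR1C2 and ANGPT1 were lost. LAMB3 was lost without MYC+shUVSSA replicate 1, and TFRC was kept in 1 of 8 such fits, while without MYC+shUVSSA replicate 2 the test over all windows called 51 bodies. The 4 body lists became 0 without control replicate 1, 1 without MYC+shUVSSA replicate 1 and 2 without MYC+shUVSSA replicate 2, and the chaperone promoters were not called without control replicate 2 or MYC+shUVSSA replicate 2, while without MYC+shUVSSA replicate 1 there were 4 promoter lists. SIK1, AGPAT5, SGK1, PLAU, LPPR3 and MIR4260 were kept in all 8 fits. DDIT4 was lost without control or MYC+shUVSSA replicate 2, CSF3 without control or MYC+shUVSSA replicate 1, IL1B without control replicate 2 or MYC+shUVSSA replicate 1, and WDR43 without these or control replicate 1. SNORD49A was lost without the same 3 libraries as WDR43, SFN was kept in 4 of 8 fits and POP5 in 3 of 8. Of the active promoters 1, of the transcript with no official symbol that rose with shUVSSA, rose here too, and this count became 9 without control replicate 1, 3 without control or MYC replicate 2, and 4 and 19 without MYC+shUVSSA replicate 1 and 2.

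**Figure D3:**
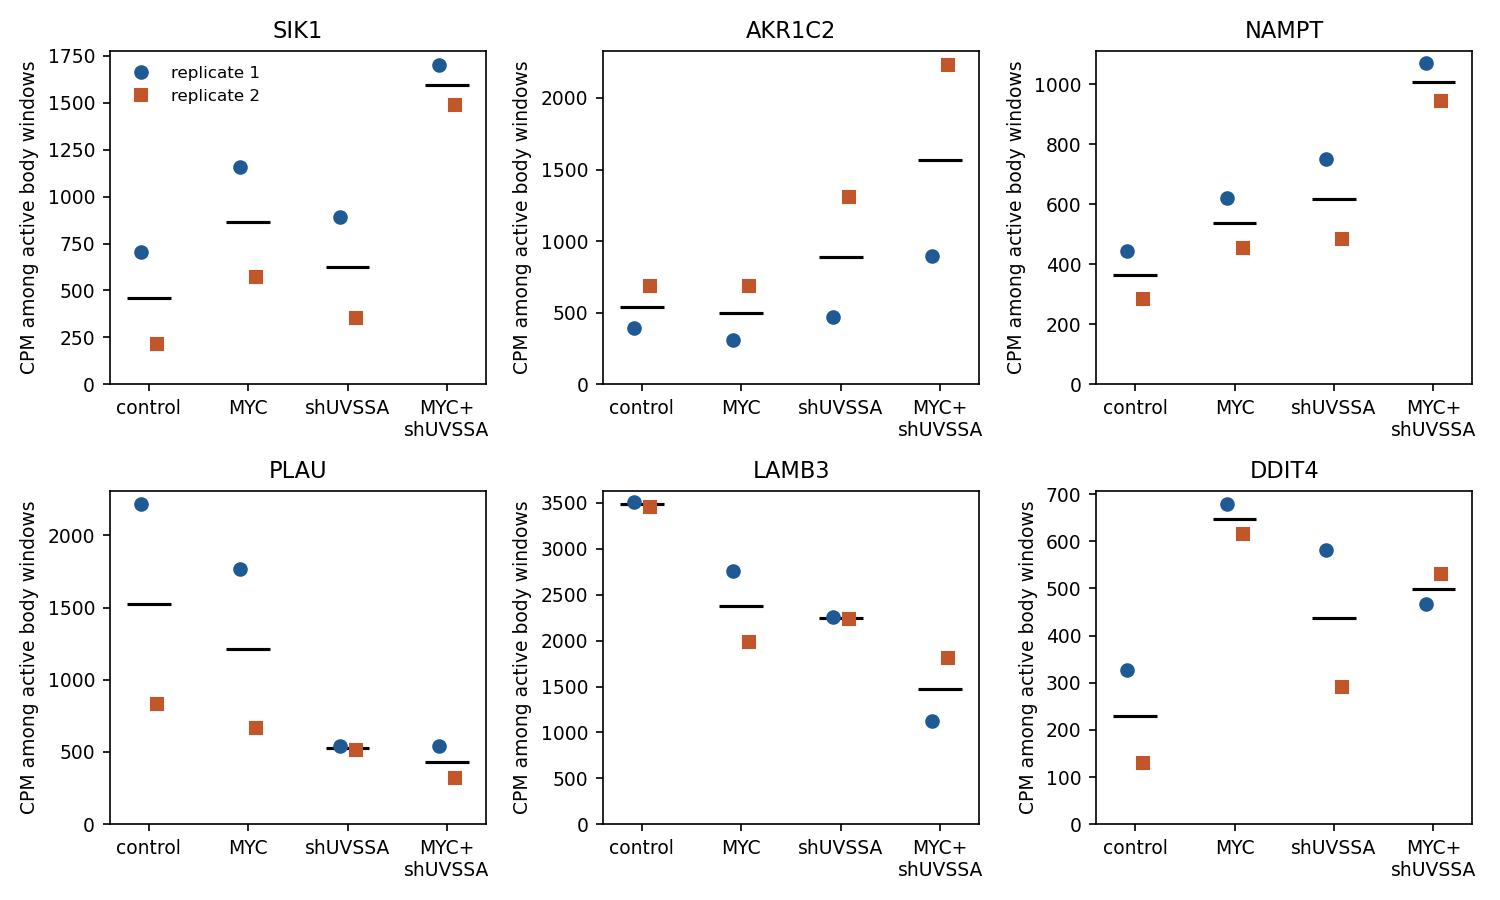
CPM among active body windows of SIK1, AKR1C2, NAMPT, PLAU, LAMB3 and DDIT4 in each library, by group, with points for libraries and bars for group means. SIK1 was highest in MYC+shUVSSA libraries (1596 ± 151 CPM) and LAMB3 lowest there (1471 ± 486 CPM).

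The interaction of MYC and shUVSSA asked whether MYC induction acted differently on RNAPII in cells with the UVSSA hairpin. Ribosomal protein genes (62 of 65 below 0, median -0.73, adjusted p = 9.06e-10) and histone genes (28 of 30, -0.85, 2.74e-07) were called for a negative interaction by camera with a preset correlation, without each of the 8 libraries as well. Their medians were 0.53 and 0.47 for MYC against control but -0.28 and -0.45 for MYC+shUVSSA against shUVSSA on the TMM scale. With loess offsets the histone medians were negative in both (-0.09 and -0.31), and those of ribosomal proteins were 0.14 and -0.17. Neither interaction was called with an estimated correlation (adjusted p = 0.560 with an estimated correlation) or with loess offsets, where the medians were -0.23 (adjusted p = 0.103) and -0.20 (0.646). Chaperone genes (15 of 19, median -0.88, adjusted p = 0.00239), splicing factors (33 of 40, -0.49, 0.0103) and MYC-induced genes (33 of 46, -0.38, 0.0314) were called too, and loess offsets left none of the 5 called. NPM1 stood at 311 ± 50.9 CPM in control and 588 ± 130 CPM in MYC libraries, but at 430 ± 47.5 CPM in shUVSSA and 430 ± 8.43 CPM in MYC+shUVSSA libraries. HSPA5 stood at 214 ± 24.9, 384 ± 165, 216 ± 42.6 and 181 ± 100 CPM in control, MYC, shUVSSA and MYC+shUVSSA libraries. Promoters of 7 blood and immune markers were called in the other direction (6 of 7 above 0, median 2.22, adjusted p = 0.0234), although this list was called in 0 of the 8 fits without a library. CD14 passed when adjusted over the list alone (log2 4.52, adjusted p = 0.00418).

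With an estimated correlation the interaction p was 0.593 for splicing, 0.560 for chaperones and MYC-induced genes and 0.707 for the blood and immune promoters (adjusted), so 0 were called. On active genes with the replicate block, tested at the preset correlation only, histones (median -0.38, adjusted p = 5.17e-05), ribosomal proteins (-0.25, 0.0164) and chaperones (-0.51, 0.0164) were called. In this fit 0 lists were called without control replicate 1 (smallest adjusted p = 0.136) and histones alone without MYC replicate 1 (median -0.25, adjusted p = 0.0270). Ribosomal proteins were also lost without shUVSSA or MYC+shUVSSA replicate 1 (adjusted p = 0.181 and 0.260), and chaperones without shUVSSA or MYC+shUVSSA replicate 2 (0.377 and 0.360). Of single genes, 0 active body windows and 1 active promoter window, SLC10A5, passed the interaction. Its promoter counts were 9 and 15 in control, 25 and 42 in MYC, 31 and 33 in shUVSSA and 0 and 0 in MYC+shUVSSA libraries. Adjusted over the list alone, those that passed included the promoters of ERCC4, a repair endonuclease at 0 in both MYC+shUVSSA libraries, and of LOX (log2 2.74, adjusted p = 0.0287). Over all windows edgeR gave 586 bodies higher and 556 lower, and 266 promoters higher and 251 lower, at an unadjusted p under 0.05, while DESeq2 called 0 bodies and 3 promoters. The smallest interaction p values among bodies were those of OR4K13, TENM2, OTOGL, MIR4780 and ADRB1 (positive) and METTL1, FICD, NLK, ADCY10 and SNORA54 (negative). Among promoters they included those of MIR4503, CD96, PRKD3, DEFA9P and CD14 (positive) and SLC10A5, MIR548AC, VDAC3 and MIR575 (negative). METTL1, an enzyme that methylates transfer RNA, stood at 36.6 ± 8.93 CPM in control, 76.5 ± 8.80 in MYC, 59.6 ± 13.1 in shUVSSA and 13.9 ± 6.34 in MYC+shUVSSA libraries (adjusted p = 0.938). The 5 body lists became 3 without control, MYC or shUVSSA replicate 1, 2 without MYC+shUVSSA replicate 2, 10 without MYC+shUVSSA replicate 1, 11 without control replicate 2 and 13 without MYC or shUVSSA replicate 2. The 1 promoter call became 0 without MYC, shUVSSA or MYC+shUVSSA replicate 1, 6 without control replicate 1, 4 without control replicate 2 and 12 without MYC+shUVSSA replicate 2. Chaperones were lost without MYC replicate 1 or MYC+shUVSSA replicate 2, and splicing and MYC-induced genes without control, MYC or shUVSSA replicate 1 or MYC+shUVSSA replicate 2. Among active bodies 5 were called without MYC+shUVSSA replicate 2 and 1 without MYC replicate 2, and without MYC+shUVSSA replicate 2 the test over all windows called 16 bodies.

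The correlation of the responses to MYC without and with shUVSSA was near 0, but it cannot show that the responses differ. Across 24144 body windows, which are not independent replicates, the log2 ratios of MYC against control and of MYC+shUVSSA against shUVSSA had a Pearson correlation of 0.00732 and a Spearman correlation of -0.00777, and across 10796 promoters 0.00976 and 0.00247. The responses to shUVSSA without and with MYC correlated at 0.0142 (Spearman 0.0107) across bodies and 0.0254 (0.0621) across promoters. Among active genes alone the correlations were higher, at 0.0783 for MYC and 0.192 for shUVSSA across bodies, and PLAU fell in both shUVSSA comparisons. The response to MYC in control cells correlated at 0.135 between its own 2 replicates across active bodies, which limits how far it can correlate with any other response.

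The promoter-to-body ratio was lower in the 4 libraries with shUVSSA than in the 4 without. This ratio of counts per kb over 3392 genes, a measure added after the data were seen, was 1.78 ± 0.156 in control, 1.71 ± 0.0358 in MYC, 1.56 ± 0.0205 in shUVSSA and 1.36 ± 0.147 in MYC+shUVSSA libraries. The 4 libraries with shUVSSA had a mean of 1.46 ± 0.143 against 1.75 ± 0.101 in the 4 without, lower in 4 of 4 libraries (exact two-sided permutation p = 0.0286 over 70 splits, and 0.0556 over the 36 splits within replicate numbers, the lowest those can give). With the silent-gene background subtracted, the means were 1.72 ± 0.185 and 2.07 ± 0.194 (exact permutation p = 0.0571 over 70 splits), with ranges that overlapped across replicate numbers (1.48 to 1.92 and 1.84 to 2.31). Within each replicate number both shUVSSA libraries lay below both others (at most 1.78 against at least 1.84 in replicate 1, and at most 1.92 against at least 2.08 in replicate 2), again the lowest exact permutation p of 0.0556. The difference was -0.284 before and -0.343 after the subtraction. Silent genes, whose ratio should not depend on RNAPII, stood at 0.893 ± 0.0264 and 0.923 ± 0.00727, a difference of -0.0299 with overlapping libraries (exact permutation p = 0.0857). Gene by gene the median log2 change of the ratio was -0.21 for shUVSSA against control, with 61.7% of genes below 0, and -0.43 for MYC+shUVSSA against MYC, with 70.0% below 0. By edgeR, SLC10A5 was the 1 gene called in each of the comparisons with MYC and with shUVSSA and in the interaction. In the other 3 comparisons edgeR called 0 genes, with 74, 141 and 378 at an unadjusted p under 0.05 for MYC, shUVSSA and MYC+shUVSSA against control. Without MYC+shUVSSA replicate 2 the calls numbered 53 against MYC, 43 against shUVSSA, 55 against control and 12 in the interaction.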

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

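The fits of active genes with the replicate block, the test of S phase genes for the histone pattern and the count of calls by group over pairings were chosen only after the result was seen. The interaction of MYC and shUVSSA was called for 5 lists in body windows and 1 in promoter windows, which is what brought them here. The medians (log2) were -0.73 for ribosomal proteins, -0.85 for histones, -0.88 for endoplasmic reticulum chaperones, -0.49 for splicing factors and -0.38 for MYC-induced genes in bodies, and 2.22 for blood and immune markers at promoters. The ribosomal protein and histone calls held without each library, but with loess offsets against abundance neither was called (medians -0.23 and -0.20, adjusted p = 0.103 and 0.646). Chaperones were lost without MYC replicate 1 or MYC+shUVSSA replicate 2, splicing and MYC-induced genes without control, MYC or shUVSSA replicate 1 or MYC+shUVSSA replicate 2, and the 7 blood and immune promoters, some of them near the floor, in all 8 such fits. With an estimated correlation 0 of these lists were called by camera.

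The first pattern weighed was the rise of 12 lists in bodies of MYC against control libraries. The median score difference from the control mean was 0.545 (log2) in MYC replicate 1 and 0.170 in MYC replicate 2, a ratio of 0.312 that lies between what the higher ChIP enrichment of MYC replicate 1 would give as the cause (at most 1/4) and what it would forbid (at least 1/2), so that explanation stays open. A gain of signal that depends on abundance has the values it needs: loess offsets left 3 of the 12 lists called. Those were MYC-induced genes (adjusted p = 0.00573), nucleotide synthesis and the integrated stress response (0.0316 each). Against genes of matched abundance, MYC-ER induction raising RNAPII at MYC target genes had both induced libraries above both others in 3 of 6 comparisons, which leaves it open as well. The inducing drug was given to the same libraries, so its own effect was not tested apart from that of MYC.

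The second pattern was the fall of histone genes in MYC+shUVSSA against MYC libraries. The tables argue against 1 replicate pair alone, since the median log2 ratio was -0.64 within replicate 1 and -0.37 within replicate 2, with 26 of 30 genes lower in both. Fewer cells in S phase was taken to lower the DNA replication and G1/S list too, but its median was 0.21 (0.32 and 0.11 within the replicates). That list mixes G1/S with S phase genes and so cannot tell fewer cells in S phase from cells held before it. A loss of signal that depends on abundance cannot be told apart from an effect on histone genes: against genes of matched abundance the difference was -0.19, with -0.13 and -0.01 in MYC+shUVSSA and 0.02 and 0.21 in MYC libraries. Without MYC replicate 1 or MYC+shUVSSA replicate 2 the list was not called, so a biological reading is no more than open.

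The third pattern was that active bodies were called mostly in comparisons with MYC+shUVSSA. Of 24 pairings of the replicate 1 with the replicate 2 libraries, only the real one gave as many as 95 calls, summed over the 6 pairs of groups. The highest other gave 50. Of the 95, 86 were in the 3 comparisons with MYC+shUVSSA, against at most 49 in the other pairings. The group with the most calls exceeded the comparisons without it by 77 calls, against at most 48 in the other pairings. The share is 1 of 24 at best, for a fit chosen after the data were seen, so chance cannot be excluded. The log2 ratios against MYC within replicate 1 and within replicate 2 correlated at 0.203 (95% bootstrap interval 0.158 to 0.247 over 2000 resamples). That met the bar set against noise of the MYC+shUVSSA libraries, but the interval reaches below the bar. Its use was settled after the value was seen, and windows are not independent replicates. The correlation was 0.228 against control, but 0.133 against shUVSSA, no higher than the 0.135 of MYC against control. Noise is therefore not decided for the pattern as a whole. A lower ChIP enrichment of the MYC+shUVSSA libraries would move genes alike in both replicates and was not tested apart from an effect of the UVSSA hairpin. Without MYC replicate 1 the calls against MYC fell from 44 to 2, 2 of them shared.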

How the results depend on the processing

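The fit of active genes with the replicate block, voom, the exclusion of 2 libraries together and the promoter-to-body ratio were chosen only after the result was seen. Comparisons are given in the order MYC against control, shUVSSA against control, MYC+shUVSSA against MYC, against shUVSSA and against control, then the interaction. The planned trend with gene length was not run, as the body windows have 1 length, and a choice among several entries per gene did not apply.

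Against 0 calls with edgeR over all body windows (681, 766, 1601, 1560, 1385 and 1142 at an unadjusted p under 0.05), active genes with the replicate block gave 1, 1, 44, 5, 37 and 0, voom on the same genes 1, 1, 21, 1, 33 and 0, and DESeq2 1 against MYC and 2 against control. Active genes without the block gave 0 in each comparison. At promoters, edgeR with no filter called 1, 2, 7, 8, 8 and 2, background scaling 1 each against MYC, against shUVSSA and in the interaction, active genes alone 2 against shUVSSA and 1 in the interaction, and without MYC replicate 1 and MYC+shUVSSA replicate 1 together 2 for shUVSSA. Active promoters with the block gave 0, 1, 2, 4, 1 and 1, voom 0, 1, 10, 3, 21 and 4, and DESeq2 0, 0, 6, 8, 3 and 3.

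For lists, camera with an estimated correlation and fry, run over all tested windows, called 0 in every comparison. With loess offsets the body lists numbered 3, 0, 0, 0, 1 and 0 and the promoter lists against MYC 0. Background scaling gave 2 body lists for shUVSSA, 8 against MYC and 2 against control, and 5 promoter lists in the interaction. Active genes with the block, tested at the preset correlation only, gave 0, 0, 1, 1, 4 and 3 body lists and 0 promoter lists. Without MYC replicate 1 and MYC+shUVSSA replicate 1 together there were 4 body lists for MYC, 0 against MYC, 1 against control and 3 in the interaction, and 2, 6, 4 and 0 promoter lists against MYC, shUVSSA, control and in the interaction. The replicate block alone gave 2 promoter lists in the interaction. Some directions turned for MYC against control: loess offsets gave -0.0865 for histones and -0.120 for NF-kB, active genes with the block turned the proteasome list lower by camera with a median of 0.0705, and without the 2 libraries the medians were -0.0216 for MYC-repressed, -0.0816 for immediate early and -0.171 for NF-kB genes.

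Leaving out each library in turn, which left 1 library in its group, gave these ranges. Without MYC+shUVSSA replicate 2 that group rested on replicate 1, the library with the most windows at 0 (31.5%). Body lists numbered 4 to 20, 0 to 11, 0 to 11, 0 to 3, 0 to 5 and 2 to 13, and promoter lists 0 to 6, 0 to 0, 0 to 14, 0 to 6, 0 to 4 and 0 to 9. Active bodies with the block numbered 0 to 5, 0 to 2, 2 to 53, 0 to 15, 11 to 46 and 0 to 5, and promoters 0 to 4, 0 to 9, 0 to 39, 0 to 21, 1 to 19 and 0 to 12. Over all windows, bodies called were 0 to 67 against MYC, 0 to 73 against shUVSSA, 0 to 51 against control and 0 to 16 in the interaction, each maximum without MYC+shUVSSA replicate 2, and promoters 0 to 3, 0 to 2, 0 to 1, 0 to 2, 0 to 2 and 0 to 3. Genes with a changed promoter-to-body ratio numbered 0 to 1, 0 to 1, 0 to 53, 0 to 43, 0 to 55 and 0 to 12. For MYC against control the medians of MYC-repressed, immediate early and NF-kB genes were -0.0238, -0.0778 and -0.175 without MYC replicate 1 and 0.70, 0.73 and 0.73 without MYC replicate 2. Against MYC, immediate early genes were at 0.0200 and NF-kB genes at 0.383 without MYC replicate 1, and at -0.904 and -1.002 without MYC replicate 2.

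The enrichment of MYC over control ranged from 1.10 to 1.77 in bodies and 1.02 to 1.68 at promoters, lowest without MYC replicate 1, and with genes of other tissues as background MYC+shUVSSA over control was 1.14 in bodies and 0.955 at promoters. The correlation of MYC effects was 0.0783 in active bodies and 0.0724 with the block, and -0.0543 to 0.0567 in bodies and -0.0451 to 0.0365 at promoters without a library. That of shUVSSA effects was 0.192 and 0.178 in active bodies, 0.116 and 0.109 at active promoters and -0.00369 with loess offsets in bodies, and -0.0183 to 0.0301 and -0.0305 to 0.0599 without a library. With genes active in both windows the promoter-to-body ratio was called for 0 genes against MYC, 0 against shUVSSA, 1 against control and 0 in the interaction. With background subtracted the differences were -0.212 for the promoter to body ratio, MYC minus control, and -0.579 for the promoter to body ratio, MYC+shUVSSA minus control. Among the alternatives, counts of genes called by the fixed test, 0 in each comparison, stayed at 0 in 205 cases and moved in 57. Counts among active genes with the replicate block stayed within 1.5 times in 51 and moved in 69. Counts of genes with a changed promoter-to-body ratio did so in 31 and 23, and counts of called lists in 84 and 96. Single called lists kept their call in 391, lost it in 311 and turned in 11. Named genes include those that did not pass, and in 1596 cases they kept the same status, called or not. They lost a call in 180 and gained it in 25.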

Other observations

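The summaries of silent windows and of genes tied to replicate number were chosen only after the result was seen. Of the 29 lists tested, 11 were called in no comparison. The smallest adjusted p were 0.0850 for nucleotide excision repair genes (promoters, MYC+shUVSSA against MYC, median log2 -0.37), 0.0610 for the RNAPII machinery (bodies, MYC against control, 0.24), 0.0545 for oxidative phosphorylation (same, 0.09), 0.0790 for p53 targets (same, 0.10) and 0.162 for hypoxia genes (same, 0.14). For MYC+shUVSSA against MYC they were 0.0887 for interferon genes (promoters, -0.17), 0.128 for basal markers (promoters, -0.27), 0.160 for mesenchymal genes (promoters, 0.45) and 0.161 for glycolysis (bodies, -0.31). Cell death genes reached 0.358 (promoters, MYC+shUVSSA against shUVSSA, 0.44) and luminal genes 0.390 (bodies, interaction, 0.15).

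Silent olfactory receptor promoters held counts that varied far more than counting error. Their variance over mean was 1.71 to 12.9 across libraries, and 1.53% to 40.9% of them were at 0 where a Poisson spread gives at most 0.921%. The promoter and body counts of silent genes had Spearman correlations of 0.0640 to 0.314.

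The share of counts in the 32 mitochondrial windows ranged from 0.209% in MYC replicate 1 to 1.53% in control replicate 1. Among active genes, 172 body and 17 promoter windows differed between the replicate numbers in edgeR.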
